A study of Mus musculus with 6 samples.

How the data were processed

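Expression was measured on 6 one-colour (Cy3) Agilent arrays of 1 design, 2 each for sorted lung myofibroblasts of bleomycin-treated mice, sorted steady-state fibroblasts of untreated mice and homogenates of untreated lung. Groups and replicate numbers were taken from the labels. The deposited scanner files hold spot intensity values as the authors' software, Agilent Feature Extraction 12.0.3.1, wrote them, per the file headers. Per the file headers its processed signal had local background and a spatial trend subtracted, was multiplicatively detrended within the array, and had small values replaced by positive surrogates. No scaling between arrays had been applied to it. The authors also deposited a table of normalized intensity values. Set against the scanner values, each of its columns was the processed signal times 1 constant per array, which brought the 2% trimmed mean of each array to about 2500. The constants were 5.46 and 5.17 for myofibroblasts, 6.79 and 6.93 for fibroblasts, and 5.98 and 6.26 for homogenates. The method behind that table is not given in the sources used here, and the authors' group means were not used.

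The main values were log2 of the processed signal minus the log2 of each array's 75th percentile, which was 224 and 225 for myofibroblasts, 233 and 230 for fibroblasts, and 282 and 270 for homogenates. Each array held 59305 spots that are not controls, for 56605 probes. Spots marked as outliers were left out and spots of 1 probe averaged. The files carry a transcript accession and no gene name, so probes were named through a RefSeq gene table, matched without versions. Of the probes, 32994 matched 1 gene each, for 22909 genes, and 23611 had no name here. For the 7897 genes with more than 1 probe, the probe with the highest mean signal stood for the gene. Probes of a gene that were called in opposite directions occurred in 2 genes between the sorted groups, 4 between fibroblasts and homogenate and 10 between myofibroblasts and homogenate. Among the genes eligible to be named, 41 of 163, 41 of 168 and 34 of 177 other probes gave another call than the main one. Other probes called in the direction opposite to the called main one numbered 0, 0 and 1.

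A gene was tested in a comparison when its probe was well above background on both arrays of at least 1 of the 2 groups. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 6 arrays in 1 fit of 3 groups, so that 3 residual degrees of freedom, 5.57 with the prior, set the spread. P-values were adjusted by Benjamini-Hochberg over the genes tested in the comparison and a gene was called at an adjusted p under 0.05. SE is limma's standard error of the log2 difference. The tests, the 30 gene lists, the list of sort markers and the rule for naming genes were fixed before the data were examined. A list needed 3 tested members, camera used a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. With an estimated correlation camera works with the 3 residual degrees of freedom. Muc16, a mesothelial gene, has no named probe here. All arrays came from 1 slide and 1 scan, so neither could be a block. The sorted samples lay in 1 row of the slide and both homogenates in the other, so slide row and homogenate cannot be told apart.

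The genes named by that rule were the 3 sort markers, the 8 largest changes each way between the sorted groups (4 each way in the other comparisons) among called genes above background on all 4 arrays, and the 3 largest bounded changes each way (2 in the others). The rule added the 2 to 4 most changed tested members of each list and Acta2, Col1a1, Itga8, Cd248 and Tcf21, and left out predicted genes and clones. Of the genes this rule selects, 1 was left out of the text and is not reported here. Genes shown only for a disagreement between probes, Loxl2 among them, and sex-linked genes other than Ddx3y were chosen after their values were seen.

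Alternatives were normexp background correction, which used the median spot signal in place of the mean one the plan named, quantile and median scaling, the authors' table, the filter on dim probes, a floor, the probe rule, the arrays in the fit, the variance trend, the threshold, the replicate number as a block, and leaving out each array. Array weights per group and the removal of genes over 2-fold apart between the fibroblast arrays were added after the data were seen. The fit was tested on simulated data with 50 genes changed by each fold among 16006. Between the sorted groups it called 0% of those changed 2-fold, 26% at 4-fold, 64% at 8-fold and 74% at 16-fold, all in the right direction, with 3 unchanged genes called. Of 20 unchanged lists, 0, 0 and 1 passed camera in the 3 comparisons. The simulated noise was independent between genes and had the same spread in every group. It therefore cannot show how camera behaves with correlated genes, or how the fit behaves where the groups differ in spread. Between the sorted groups 85 simulated genes were called in all, against 2758 of 16006 in the data. Benjamini-Hochberg adjustment is stricter where fewer genes change, so the simulated shares called cannot be carried over to the data. Figures were drawn with matplotlib 3.10.9. Genome positions were not used here.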

Results

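Gene expression was measured in 3 kinds of mouse lung sample with 1-colour Agilent arrays, 2 arrays per group and 6 in all. Myofibroblasts, the contractile and matrix-producing cells of injured tissue, were sorted as CD49e-positive, Sca-1-negative, lineage-negative cells from lungs of mice given bleomycin, a drug used to induce lung fibrosis. Steady-state fibroblasts were sorted as CD140a-positive, lineage-negative cells from untreated lungs. Homogenates of whole untreated lung were the controls. A set was 50000 cells per the labels, and 5.8 ng of RNA was labelled. Cell gate and bleomycin treatment changed together, so no comparison separates them. Nothing in the labels says that the 2 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

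Probes well above background made up 66.5% and 65.5% of the spots on the myofibroblast arrays, 67.0% and 66.2% on the fibroblast arrays, and 71.4% and 73.4% on the homogenate arrays. No spot was saturated. The small number of arrays limits the precision of each value. The 2 fibroblast arrays lay further apart than the arrays of either other group. Between them, 3539 of 15057 genes well above background on both (23.5%) differed by more than 2-fold, against 7.84% for the myofibroblast arrays and 2.83% for the homogenate arrays. The SD of the log2 difference between the arrays of a group was 0.88 for fibroblasts, 0.58 for myofibroblasts and 0.39 for homogenates. Among the genes in the brightest quartile it was 0.78, 0.38 and 0.19.

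**Figure D1:**
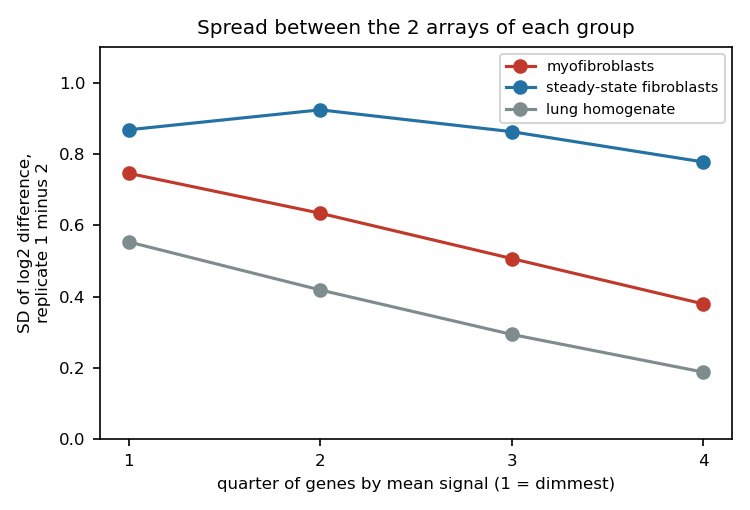
SD across genes of the log2 difference between the 2 arrays of each group (y axis, log2 units), for genes sorted into quartiles by mean signal (x axis, 1 the dimmest), with 1 line per group. The fibroblast line lies above the others in every quartile, at 0.87 in the dimmest and 0.78 in the brightest.

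The genes of the sort markers were read first, as a check of the labels and not as findings. Itga5, which encodes CD49e, was higher in myofibroblasts than in steady-state fibroblasts by 4.01 ± 0.35 on the log2 scale (SE, n = 2 per group, limma adjusted p = 0.00324). Ly6a, which encodes Sca-1, was lower in myofibroblasts at -1.94 ± 0.32 (adjusted p = 0.0168), and so was Pdgfra, which encodes CD140a, at -2.36 ± 0.39 (adjusted p = 0.0180). Pdgfra was higher in fibroblasts than in homogenate by 2.80 ± 0.39 (adjusted p = 0.00647). Leaving out either myofibroblast array or either homogenate array ended the calls of Ly6a and Pdgfra between the sorted groups (adjusted p up to 0.0798 and 0.0867), and leaving out either homogenate array ended that of Pdgfra against homogenate (up to 0.0548).

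**Figure D2:**
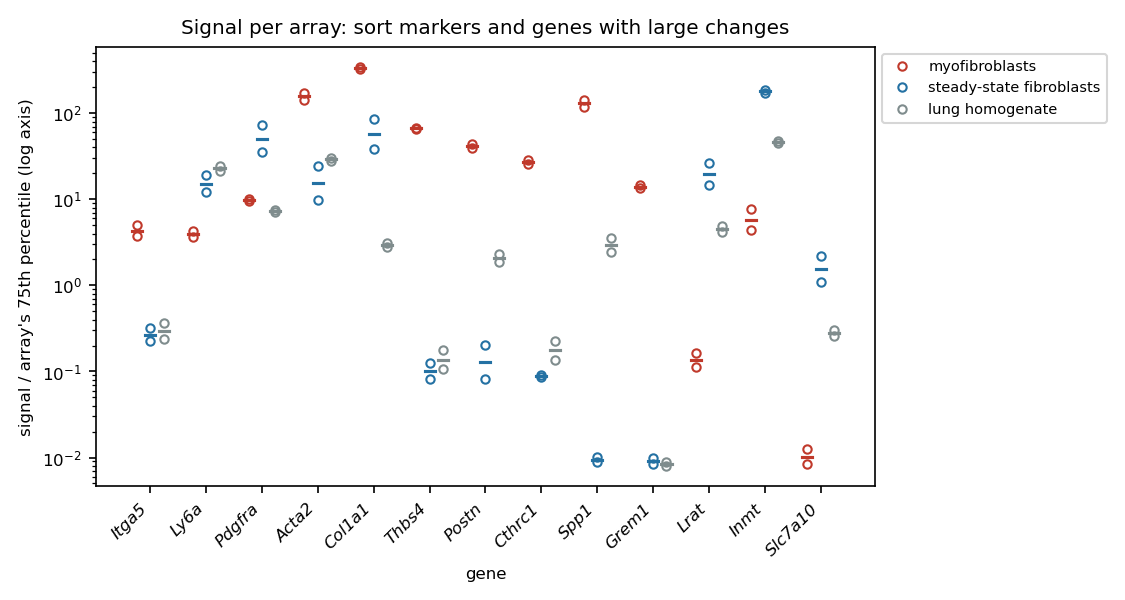
Signal of 13 genes on each of the 6 arrays, relative to the array's 75th percentile (y axis, log scale), with open circles for arrays and bars for the geometric mean of each group. Circles near 0.01 (Spp1 and Grem1 in fibroblasts, Grem1 in homogenate, Slc7a10 in myofibroblasts) were not well above background, and Thbs4 stands at 66.6 in myofibroblasts against 0.101 in fibroblasts.

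The comparison of main interest, given by the series title, set myofibroblasts against steady-state fibroblasts. By list tests given below, cell cycle, matricellular and fibrillar collagen genes were higher in myofibroblasts and genes of alveolar and lipid-storing fibroblasts lower. Their camera adjusted p was 1.19e-12, 1.48e-06, 0.000359 and 0.00136, and adjusted p = 0.148, 0.148, 0.268 and 0.268 with an estimated correlation. The largest increases measured on both sides were in Thbs4, a matricellular protein, at 9.36 ± 0.37 (log2, SE, n = 2 per group), Postn (periostin) at 8.34 ± 0.46, Cthrc1 at 8.25 ± 0.32, the intermediate filament gene Des at 7.28 ± 0.62 and Tnc (tenascin C) at 7.0 ± 0.28. Kif26b, a kinesin family gene, followed at 6.96 ± 0.36, then the mitotic gene Depdc1a at 6.16 ± 0.27 and Inhba, which encodes the activin A subunit, at 6.12 ± 0.25. The largest decreases among such genes, predicted genes aside, were in Lrat, which esterifies retinol for storage, at -7.16 ± 0.38, Gprasp2 at -5.59 ± 0.58, Eya2 at -5.59 ± 0.51 and Ppp4r4 at -5.52 ± 0.55. Adh7, a retinol-oxidising dehydrogenase, stood at -5.24 ± 0.41, Dner at -5.19 ± 0.55, Mapt at -5.07 ± 0.96 and Inmt, a methyltransferase, at -4.95 ± 0.33. Adjusted p ran from 0.000935 to 0.0245 over these 16 genes. The call of Mapt ended when either myofibroblast or either homogenate array was left out (adjusted p up to 0.108), and its 3 other probes gave -3.85, -1.78 and -1.32 (adjusted p = 0.0196, 0.0371 and 0.0523). Another probe of Eya2 gave -0.06 (adjusted p = 0.911).

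Other genes were read above background in one group alone. Their fold is a lower bound, taken against the lowest signal that counted as well above background on the dimmer arrays, or the gene's own signal where that was higher. A gene read on 1 array of a group is bounded in the same way, with its other array put at that signal. Spp1 (osteopontin) was at least 3030-fold higher in myofibroblasts, Grem1, a secreted BMP antagonist, at least 327-fold, and Lrrc15 at least 187-fold (adjusted p = 0.000241 for each). The sulfotransferase gene Sult1e1 was at least 39.1-fold lower, Hoxc4 at least 41.0-fold and the amino acid transporter gene Slc7a10 at least 38.1-fold lower (adjusted p = 0.00128, 0.00766 and 0.00132).

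At an adjusted p under 0.05, 2758 of 16006 tested genes differed, 1475 higher and 1283 lower in myofibroblasts. The homogenate arrays enter this count only through the shared estimate of spread, and with the 4 sorted arrays alone it was 1061. That estimate takes the spread as equal in all groups. The SD between arrays was 0.88 for fibroblasts, 0.58 for myofibroblasts and 0.39 for homogenates, so p-values between the sorted groups may be too small. Array weights per group, chosen after the result was seen, gave 1142 called genes. The count was 1008 or 884 without myofibroblast replicate 1 or 2, 5605 without fibroblast replicate 2, and 1061 without either homogenate array. The called genes were 53.5% higher ones in the main scaling and 46.7% with quantile normalization. They were 64.6% with median scaling and 25.4% in the authors' deposited table, settings that shifted the median of all genes by 0.14 and -0.41 on the log2 scale.

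**Figure D3:**
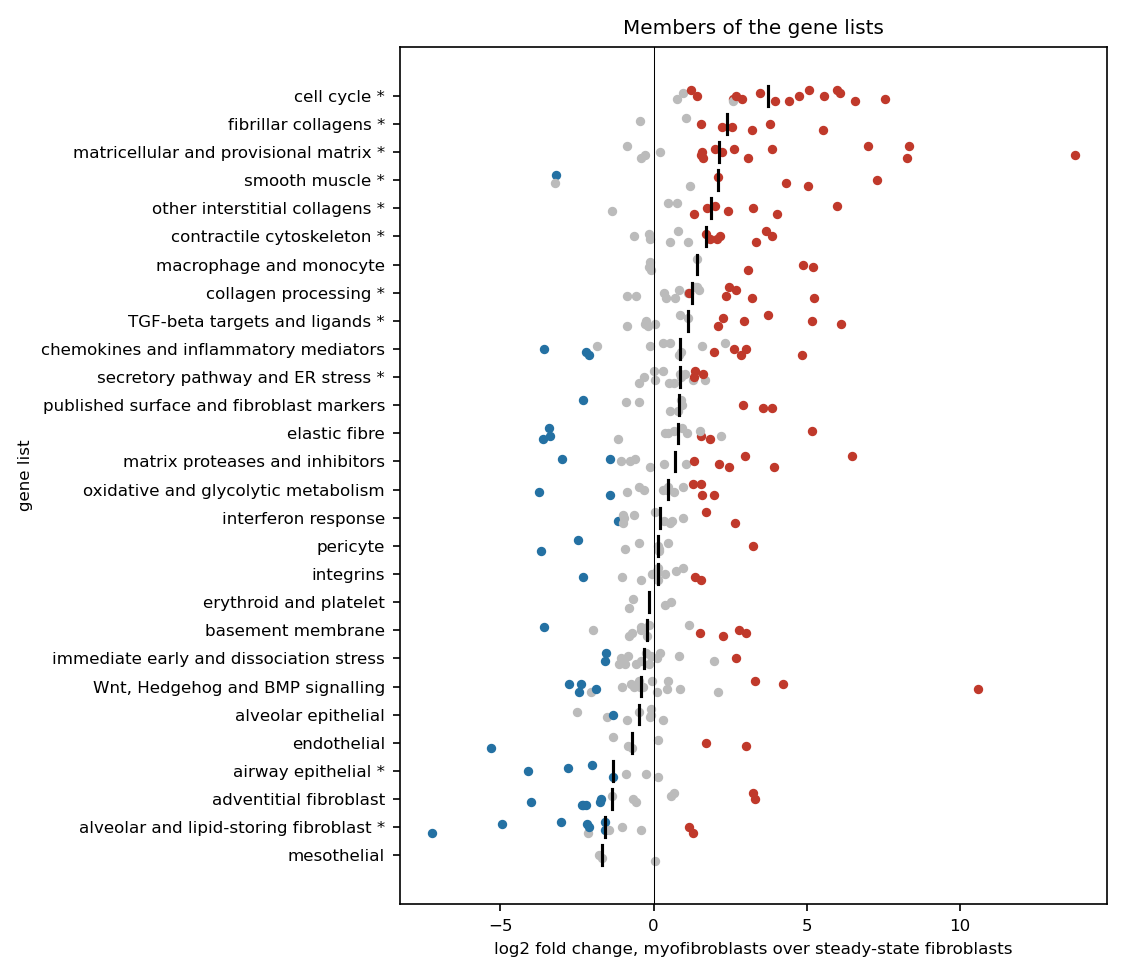
Log2 fold change of each tested gene in 28 lists, myofibroblasts over steady-state fibroblasts (x axis), 1 row per list, with red and blue points for genes called higher and lower, grey for the rest and a bar at the median. A star marks the 11 lists past camera's test at an adjusted p under 0.05, and genes not above background in one group are drawn at their fitted value, which is not a bound.

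Of 28 fixed gene lists with enough tested members, 11 passed camera's test with a preset correlation, 9 higher and 2 lower. None passed with an estimated correlation, where 5 had an unadjusted p under 0.05, while limma's fry test, which asks only whether a list moves one way, passed 16. Among the 11 lists the estimated correlation ran from -0.14 (smooth muscle) to 0.41 (fibrillar collagens). That setting also rests on the 3 residual degrees of freedom, so a lost call does not by itself show correlated members. Genes of the contractile cytoskeleton were higher in myofibroblasts. Of 13, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with camera adjusted p = 0.000571, and adjusted p = 0.148 with an estimated correlation. Acta2, the smooth muscle actin that defines the cell type, rose by 3.35 ± 0.46 (adjusted p = 0.0107), to 158 times the array's 75th percentile from 15.5. The actin-binding gene Tagln rose by 3.87 ± 0.40, the tropomyosin gene Tpm2 by 3.68 ± 0.24 and Cald1 (caldesmon) by 2.17 ± 0.27. In the smooth muscle list 4 of 7 were higher and 1 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.0469, and adjusted p = 0.268 with an estimated correlation. Des led it, with Actg2 (smooth muscle gamma actin) at 5.03 ± 0.66 and Cnn1 (calponin) at 4.31 ± 0.25. Without either myofibroblast array the calls of Acta2 (adjusted p up to 0.0679), Actg2 (0.0577) and the smooth muscle list (0.141) ended. Median scaling and the replicate number as a block ended the call of that list as well (adjusted p = 0.0725 and 0.0711). Of 9 pericyte genes, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.745, down, though the median was 0.15). Cspg4, the NG2 proteoglycan, rose by 3.26 ± 0.25, while the potassium channel genes Abcc9 and Kcnj8 stood at -3.68 ± 0.58 and -2.45 ± 0.33. Abcc9 lost its call without fibroblast replicate 1 (adjusted p = 0.0531) and Kcnj8 without myofibroblast replicate 1 (0.0544). The brightest probe of Tpm1 read -0.14 (adjusted p = 0.745) and 2 other probes 2.71 and 2.95 (adjusted p = 0.00565 and 0.00503), while a second probe of Tpm2 read 0.43 (adjusted p = 0.279) and one of Cald1 1.33 (0.106).

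Collagen genes were higher across several classes. Of 8 fibrillar collagens, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.000359, and adjusted p = 0.268 with an estimated correlation. Col1a1, a chain of type I collagen, rose by 2.54 ± 0.43 (adjusted p = 0.0181), to a relative signal of 335 from 57.4. Col11a1 rose by 5.52 ± 0.39, Col5a3 by 3.79 ± 0.32 and Col5a1 by 3.20 ± 0.46. Of 10 other interstitial collagens, 7 were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.000290, and adjusted p = 0.148 with an estimated correlation. Col8a1 led at 6.0 ± 0.36, then Col12a1 at 4.02 ± 0.29 and Col15a1 at 3.25 ± 0.25. Of 16 genes that hydroxylate, trim or cross-link collagen, 6 were higher and 0 lower (8 and 0 adjusted over the list alone), with camera adjusted p = 0.000648, and adjusted p = 0.148 with an estimated correlation. They included the prolyl hydroxylase gene P4ha3 at 5.24 ± 0.53 and the propeptidase gene Adamts14 at 3.21 ± 0.33. Without either myofibroblast array Col1a1 (adjusted p up to 0.0934) and Col5a1 (0.0713) lost their calls, and without either homogenate array Col1a1 did. A second probe of Col15a1 read 1.02 (adjusted p = 0.0755), and the brightest probe of Loxl2, a collagen cross-linking enzyme, read 0.40 (adjusted p = 0.277) where another read 3.52 (0.00524).

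Matricellular and provisional matrix genes were higher. Of 16, 12 were higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 1.48e-06, and adjusted p = 0.148 with an estimated correlation. Spp1, Postn, Cthrc1 and Tnc, given above, led them. Of 13 TGF-beta targets and ligands, 6 were higher and 0 lower (8 and 0 adjusted over the list alone), with camera adjusted p = 0.00185, and adjusted p = 0.268 with an estimated correlation. Beside Inhba, Ltbp2, a latent TGF-beta binding protein, rose by 5.17 ± 0.41 and Tgfb1 by 2.94 ± 0.39. Without fibroblast replicate 2 this list was no longer past the test (adjusted p = 0.0665), and without myofibroblast replicate 2 Tgfb1 was not (0.0601).

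Elastic fibre and basement membrane genes went both ways. Of 14 elastic fibre genes, 3 were higher and 3 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.283), with Ltbp2 up and the fibulin genes Efemp1, Fbln1 and Fbln5 at -3.61 ± 0.37, -3.41 ± 0.36 and -3.39 ± 0.35. Eln (elastin) read 1.08 (adjusted p = 0.0997) by its brightest probe and 3.54 (0.0129) by another. Of 13 basement membrane genes, 4 were higher and 1 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.738, up, though the median was -0.23). Col4a2 and Col4a1, the widespread type IV collagen chains, rose by 3.03 ± 0.27 and 2.27 ± 0.27. Col4a4, of the alveolar type IV network, was at least 2.84-fold lower, a call that ended without either myofibroblast array (adjusted p up to 0.0552). Of 14 matrix proteases and inhibitors, 6 were higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.180), with Mmp9 at least 20.6-fold higher, Timp1 at 3.94 ± 0.27 and Mmp3 at -3.00 ± 0.30.

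Cell cycle genes formed the list with the smallest p. Of 18, 15 were higher and 0 lower (18 and 0 adjusted over the list alone), with camera adjusted p = 1.19e-12, and adjusted p = 0.148 with an estimated correlation. The topoisomerase gene Top2a was at least 78.2-fold higher, the cyclin gene Ccnb1 at least 23.5-fold and Bub1, of the spindle checkpoint, at least 16-fold, none of the 3 above background on a fibroblast array. The transcription factor gene Foxm1, read on 1 fibroblast array, was at least 29.4-fold higher. In the secretory pathway and ER stress list 3 of 15 were higher and 0 lower (6 and 0 adjusted over the list alone), with camera adjusted p = 0.0105, and adjusted p = 0.249 with an estimated correlation. The translocon gene Sec61b rose by 1.60 ± 0.30, the disulfide isomerase gene Pdia4 by 1.36 ± 0.25 and the COPII coat gene Sec24d by 1.31 ± 0.27, all from the rough ER and its exit. Each of these 3 calls ended when either myofibroblast or either homogenate array was left out (adjusted p up to 0.112, 0.108 and 0.136), and with quantile normalization the list had an adjusted p of 0.208.

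Genes of alveolar and lipid-storing fibroblasts were lower, while the adventitial list did not pass. Of 13 genes of alveolar and lipid-storing fibroblasts, 7 were lower and 2 higher (9 and 2 adjusted over the list alone), with camera adjusted p = 0.00136, and adjusted p = 0.268 with an estimated correlation. Beside Slc7a10 and Inmt, the sodium channel gene Scn7a stood at -3.03 ± 0.32 and Pparg, a regulator of lipid storage, at -2.19 ± 0.38. Tcf21, a transcription factor of lipid-storing lung fibroblasts, read -1.46 ± 0.53 and did not pass (adjusted p = 0.114). Of 13 adventitial fibroblast genes, 6 were lower and 2 higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.0941). Dcn (decorin) stood at -2.34 ± 0.24 and Dpp4 was at least 3.4-fold lower, while Col15a1 rose and Sfrp1, a secreted Wnt antagonist, rose by 3.32 ± 0.62. Either myofibroblast array left out ended the calls of Pparg (adjusted p up to 0.104), Dpp4 (0.0899) and Sfrp1 (0.109), and either homogenate array left out ended those of Pparg and Sfrp1. The adventitial list itself passed with quantile normalization (adjusted p = 0.0488) and without fibroblast replicate 1 (0.00893).

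In the list of surface and fibroblast markers 3 of 10 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0823, and 0.0335 in the authors' table). The list holds Cd248 and Itga8, which the study itself put forward as fibroblast markers, so its counts are not independent evidence. S100a4 rose by 3.86 ± 0.27, the hyaluronan receptor gene Cd44 by 3.57 ± 0.44 and Thy1 by 2.93 ± 0.25. Itga8, an integrin chain, stood at -2.30 ± 0.31 (adjusted p = 0.00975), and Cd248 (endosialin) at 0.80 ± 0.24 did not pass (adjusted p = 0.0759). Without myofibroblast replicate 2 the calls of Cd44 (adjusted p = 0.0518) and Itga8 (0.0618) ended. Of 13 integrin genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.591). Among 20 genes of Wnt, Hedgehog and BMP signalling, 3 were higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.608, down, though the mean was 0.34). Grem1, given above, and the Wnt antagonist gene Dkk2 at 4.23 ± 0.38 rose, while Hhip, a Hedgehog target and inhibitor, stood at -2.76 ± 0.40 (adjusted p up to 0.0651 without either myofibroblast array).

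Mediators of inflammation and stress were mixed. Of 16 chemokines and inflammatory mediators, 5 were higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.124, and 0.0363 in the authors' table). The monocyte chemokine gene Ccl2 rose by 3.01 ± 0.31 and the neutrophil chemokine gene Cxcl2 by 2.85 ± 0.31, while the alarmin gene Il33 stood at -3.57 ± 0.36. In the interferon list 2 of 12 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.745). Of 16 immediate early and dissociation stress genes, 1 was higher and 2 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.244, and 0.0370 with quantile normalization). Fosl1, a member of the AP-1 family read on 1 fibroblast array, was at least 5.21-fold higher and the nuclear receptor gene Nr4a1 stood at -1.56 ± 0.24. Both calls ended without either myofibroblast array (adjusted p up to 0.0642 and 0.0815), and that of Nr4a1 without either homogenate array. Among 14 genes of oxidative and glycolytic metabolism, 4 were higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.423), the higher ones including the glycolytic genes Hk2 at 1.96 ± 0.40 and Pgk1 at 1.54 ± 0.36. Ppargc1a, a regulator of mitochondrial genes, was at least 6.10-fold lower. Leaving out either homogenate array or myofibroblast replicate 1 ended all 3 of these calls (adjusted p up to 0.120, 0.165 and 0.0754), as did fibroblast replicate 1 for Ppargc1a and myofibroblast replicate 2 for Hk2 and Pgk1.

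Markers of other lung cells also differed between the sorted groups. Of 7 airway epithelial genes, 4 were lower in myofibroblasts and 0 higher (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0105, and adjusted p = 0.268 with an estimated correlation. Scgb1a1, the club cell secretoglobin, read 12.9 times the 75th percentile in myofibroblasts, 90.3 in fibroblasts and 608 in homogenate, and Cyp2f2, read on 1 myofibroblast array, was at least 17.1-fold lower. Without myofibroblast replicate 1 the call of Scgb1a1 ended (adjusted p = 0.0513). Of 7 macrophage and monocyte genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0544). This list passed without either myofibroblast array (adjusted p = 0.0108 and 0.0114) or either homogenate array (0.0430), with quantile normalization (0.0498) and in the authors' table (0.0290). Tyrobp, an adaptor of myeloid receptors, was at least 9.07-fold and Chil3, of alveolar macrophages, at least 13.7-fold higher, at 0.661% and 0.302% of their level in homogenate. Among 9 alveolar epithelial genes, 1 was lower (1 adjusted over the list alone, camera adjusted p = 0.117). The endothelial list had 2 of 7 higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.738). None of 3 mesothelial genes (2 lower adjusted over the list alone, 2 at an unadjusted limma p under 0.05, camera adjusted p = 0.263) and none of 4 erythroid and platelet genes (0 adjusted over the list alone, 0 unadjusted, camera adjusted p = 0.925) was called. Too few lymphocyte (1) and neutrophil (2) genes were read for a list test. Cd3e, the lymphocyte gene, read -0.33 ± 0.23 (adjusted p = 0.342), and Mmp8, of neutrophils, rose by 2.51 ± 0.27 (adjusted p = 0.00535).

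Steady-state fibroblasts were next set against the homogenates, a comparison in which the sort and the slide row changed together and sex-linked genes differed. By list tests given below, elastic fibre and fibrillar collagen genes were higher in fibroblasts and genes of macrophages, endothelium and alveolar epithelium lower. Their camera adjusted p was at most 9.33e-05, and adjusted p = 0.0722 with an estimated correlation (0.181 for fibrillar collagens). Among genes above background on all 4 arrays the largest increases were in Dner, a Notch ligand, at 5.72 ± 0.55, Vit (vitrin) at 5.01 ± 0.29, the enkephalin precursor gene Penk at 4.96 ± 0.30 and the scavenger receptor gene Scara5 at 4.94 ± 0.68. The macrophage receptor gene Marco stood at -9.32 ± 0.64, Plet1 at -8.51 ± 0.41, Shtn1 at -8.45 ± 0.58 and the MHC class II gene H2-Ab1 at -8.36 ± 0.67. Chil3 was at least 4534-fold and Tyrobp at least 1373-fold lower, while Sult1e1 was at least 40.5-fold higher. In all, 3392 of 17063 genes were called, 1380 higher and 2012 lower in fibroblasts. Only 6 arrays share the estimate of spread, and the count was 1492 or 1420 without homogenate replicate 1 or 2 and 6148 without fibroblast replicate 2. The called genes were 40.7% higher ones, but 50.7% with median scaling, which shifted the median of all genes by 0.27, 50.9% without fibroblast replicate 2, and 55.2% when only genes well above background on all 4 arrays were tested. They were 28.0% or 26.2% higher ones without homogenate replicate 1 or 2, and 29.6% at an adjusted p under 0.01.

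Ddx3y, a Y-linked gene, was at least 57.9-fold higher in fibroblasts (adjusted p = 0.000400), although the labels give 1 sex, male, for all 6 samples. The homogenates labelled male read Xist, which female cells express from the inactive X chromosome, at 26.7 and 24.9 times the 75th percentile. On the 4 sorted arrays Xist lay between 0.00836 and 0.119 and was well above background on 1. Ddx3y, Kdm5d and Uty, all Y-linked, were well above background on all 4 sorted arrays and on neither homogenate array. Eif2s3y, another Y-linked gene, was read on all 6 and was higher in fibroblasts by 4.0 on the log2 scale (adjusted p = 0.000453). Apart from Ddx3y these genes were chosen after their values were seen, and both comparisons with homogenate carry this difference.

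Of 30 lists, 24 passed camera's test, 15 higher and 9 lower in fibroblasts. None passed with an estimated correlation (smallest adjusted p = 0.0722, with 15 at an unadjusted p under 0.05), and 27 passed fry. The 9 lower lists included the lists of other lung cells. All 12 alveolar epithelial genes, 11 of 12 macrophage and monocyte genes, 10 of 11 endothelial genes, 9 of 9 lymphocyte genes and 7 of 8 airway epithelial genes were lower and 0 higher (12, 11, 10, 9 and 8 adjusted over the list alone). So were 5 of 7 mesothelial, 5 of 6 neutrophil, and 6 of 8 erythroid and platelet genes (5, 5 and 7 adjusted over the list alone). Camera adjusted p for these 8 lists ran from 4.90e-11 to 8.95e-05, and with an estimated correlation every adjusted p was 0.0722 to 0.0845. Examples were the surfactant gene Sftpc at -7.37 ± 0.23, the haemoglobin gene Hba-a1 at -7.27 ± 0.46 and the endothelial cadherin gene Cdh5, at least 294-fold lower and read on 1 fibroblast array. The brightest probe of the macrophage receptor gene Csf1r did not differ (-0.01, adjusted p = 0.991), where another read -3.95 (adjusted p = 0.00053). The cell cycle list was the ninth, with 7 of 17 lower and 0 higher (9 and 0 adjusted over the list alone), camera adjusted p = 0.000135, and adjusted p = 0.109 with an estimated correlation. Its gene Mki67 stood at -2.77 ± 0.26.

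Matrix and adventitial fibroblast genes were among the 15 higher lists. Higher were 11 of 14 elastic fibre genes (11 adjusted over the list alone), 9 of 13 adventitial fibroblast genes with 1 lower (11 and 1), 6 of 8 fibrillar collagens (6), 6 of 10 other interstitial collagens (8) and 8 of 16 collagen processing genes (9). Camera adjusted p was 4.84e-07, 1.06e-06, 9.33e-05, 5.42e-05 and 8.45e-05, and adjusted p = 0.0722, 0.109, 0.181, 0.0722 and 0.0722 with an estimated correlation. Col1a1 rose by 4.29 ± 0.43, Dcn by 4.31 ± 0.24, Fbln1 by 3.71 ± 0.36 and the eotaxin gene Ccl11 by 4.69 ± 0.37. Of 16 matricellular genes 10 were higher and 2 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.000504), and adjusted p = 0.0845 with an estimated correlation. Spp1 was at least 68.6-fold lower and Postn stood at -4.02 ± 0.46. In the protease list 8 of 13 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.000114), with Mmp3 at 3.66 ± 0.30, and adjusted p = 0.0722 with an estimated correlation. Wnt, Hedgehog and BMP genes had 10 of 19 higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 4.60e-05), with the Hedgehog effector Gli1 at 3.5 ± 0.45, and adjusted p = 0.0845 with an estimated correlation. Of 13 basement membrane genes 6 were higher and 1 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.00173), with the laminin gene Lama2 at 3.41 ± 0.31, and adjusted p = 0.286 with an estimated correlation.

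Immediate early genes, which tissue dissociation can induce, had 7 of 16 higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000749), and adjusted p = 0.0845 with an estimated correlation. Nr4a1 rose by 1.96 ± 0.24 (adjusted p = 0.00412, and 0.0547 without homogenate replicate 1). Of 16 chemokines and mediators 8 were higher and 2 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.0178), and adjusted p = 0.369 with an estimated correlation. Median scaling gave this list an adjusted p of 0.0647. Of 15 secretory pathway genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.0116), and adjusted p = 0.109 with an estimated correlation. Quantile normalization (adjusted p = 0.0669) and leaving out fibroblast replicate 2 (0.0517) ended the call of that list. The contractile list (1 of 13 higher, 0 lower, 0 and 0 adjusted over the list alone), the TGF-beta list (5 of 13 higher, 1 lower, 5 and 1 adjusted over the list alone) and the alveolar fibroblast list (6 of 13 higher, 2 lower, 7 and 3 adjusted over the list alone) passed narrowly. Their camera adjusted p was 0.0407, 0.0470 and 0.049996, and adjusted p = 0.166, 0.363 and 0.321 with an estimated correlation. All 3 calls ended when either myofibroblast array was left out (adjusted p = 0.0502, 0.0548 and 0.0548), and with normexp or quantile normalization (adjusted p up to 0.132, 0.0957 and 0.128). Those of the TGF-beta and alveolar fibroblast lists also ended with median scaling (adjusted p = 0.0710 and 0.117) and with the replicate number as a block (0.0527 and 0.0586). The contractile call also ended without either homogenate array (adjusted p up to 0.0589), the TGF-beta call without fibroblast replicate 1 (0.289) or homogenate replicate 1 (0.0590), and the alveolar fibroblast call without fibroblast replicate 2 (0.251) or homogenate replicate 2 (0.0586). Not past the test were the surface marker list (5 of 10 higher, 4 lower, 5 and 4 adjusted over the list alone, camera adjusted p = 0.329), smooth muscle (0 of 7 higher, 2 lower, 1 and 3 adjusted over the list alone, 0.0687) and pericyte genes (2 of 10 higher, 1 lower, 2 and 3 adjusted over the list alone, 0.706). The same held for integrins (3 of 15 higher, 3 lower, 4 and 3 adjusted over the list alone, 0.706), the interferon list (1 of 12 higher, 1 lower, 1 and 1 adjusted over the list alone, 0.901) and metabolism (0 of 14 by limma, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0.706). With median scaling (adjusted p = 0.0405) or normexp (0.0290) the smooth muscle list passed. Among single genes, Cd248 was higher by 3.56 ± 0.24 and Itga8 by 2.39 ± 0.31 (adjusted p = 0.0506 without homogenate replicate 2), while Acta2 at -0.92 ± 0.46 and Tcf21 at 1.45 ± 0.53 did not pass (adjusted p = 0.241 and 0.127).

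Myofibroblasts were last set against the homogenates of untreated lung, a comparison in which treatment and cell type both differ. Among genes above background on all 4 arrays Thbs4 led again, at 8.92 ± 0.37, with Tnc at 8.75 ± 0.28, P4ha3 at 7.71 ± 0.53 and Inhba at 7.5 ± 0.25. Grem1 was at least 360-fold and Lrrc15 at least 205-fold higher. The lowest genes above background on all 4 arrays were Sftpc at -8.71 ± 0.23, Ear1, of eosinophils and macrophages, at -8.47 ± 0.26, the endothelial gene Cd93 at -8.41 ± 0.29 and Chil3 at -8.37 ± 0.59. S100a9, of neutrophils, was at least 989-fold and Ctla2a at least 711-fold lower. Of 17163 tested genes 4612 were called, 2044 higher and 2568 lower. The called genes were 44.3% higher ones, 64.9% with median scaling and 20.6% in the authors' table, where the median of all genes moved by 0.40 and -0.50 (0.10 with quantile normalization), and 56.1% among genes well above background on all 4 arrays. The count was 2805 or 2440 without myofibroblast replicate 1 or 2, 1809 or 1724 without homogenate replicate 1 or 2, and 7287 with either fibroblast array left out or with the 4 compared arrays alone.

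Against homogenate 24 of 30 lists passed camera's test, 16 higher and 8 lower, with none past it under an estimated correlation (smallest adjusted p = 0.0536, with 15 at an unadjusted p under 0.05) and 26 past fry. Higher were 14 of 16 matricellular genes (14 adjusted over the list alone), 13 of 16 collagen processing genes (16), 14 of 18 cell cycle genes (15), 8 of 10 other interstitial collagens (8), 7 of 8 fibrillar collagens (7, with 1 lower) and 10 of 13 contractile genes (12). Camera adjusted p was 6.45e-11, 4.55e-09, 9.49e-09, 1.47e-07, 3.51e-06 and 3.51e-06, and adjusted p = 0.0536, 0.0536, 0.0657, 0.0536, 0.125 and 0.0536 with an estimated correlation. Col1a1 rose by 6.83 ± 0.43, Col5a1 by 6.94 ± 0.46, Cthrc1 by 7.27 ± 0.32, the lysyl oxidase gene Loxl3 by 4.98 ± 0.26, Tagln by 4.06 ± 0.40 and the cyclin gene Ccna2 by 3.69 ± 0.33. Acta2 rose by 2.43 ± 0.46 (adjusted p = 0.0161), a call that ended without either myofibroblast or either homogenate array (up to 0.0976). Also higher were 8 of 14 proteases and inhibitors (11 adjusted over the list alone), 9 of 14 elastic fibre genes (11, with 2 lower), 8 of 13 TGF-beta genes (9) and 9 of 15 secretory pathway genes (9). Camera adjusted p was 9.17e-06, 2.38e-05, 3.17e-05 and 6.67e-05, and adjusted p = 0.0536, 0.0549, 0.122 and 0.0549 with an estimated correlation. In the adventitial list 7 of 13 were higher and 1 lower (8 and 1 adjusted over the list alone), in the basement membrane list 9 of 13 and 1 (9 and 1), and in the Wnt, Hedgehog and BMP list 7 of 20 and 1 (9 and 2). Camera adjusted p was 0.000245, 0.000310 and 0.00213, and adjusted p = 0.160, 0.218 and 0.113 with an estimated correlation. The surface marker list had 6 of 10 higher and 1 lower (6 and 1 adjusted over the list alone), the chemokine list 8 of 16 and 3 (9 and 3) and the immediate early list 3 of 16 and 0 (3 and 0). Camera adjusted p was 0.00206, 0.00318 and 0.020, and adjusted p = 0.0890, 0.292 and 0.131 with an estimated correlation. The immediate early call ended with quantile normalization (adjusted p = 0.772) and in the authors' table (0.0754).

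The 8 lower lists were those of other cells. All 12 alveolar epithelial, 11 endothelial and 8 airway epithelial genes were lower, with 11 of 12 macrophage and monocyte, 6 of 7 mesothelial, 7 of 9 lymphocyte, 7 of 8 erythroid and platelet and 4 of 6 neutrophil genes (12, 11, 8, 11, 6, 8, 7 and 4 adjusted over the list alone, with 1 neutrophil gene higher). Camera adjusted p ran from 2.75e-09 to 0.00206, and every adjusted p was 0.0536 to 0.112 with an estimated correlation. The leukocyte antigen gene Ptprc was at least 453-fold and Cyp2f2 at least 423-fold lower, each read on 1 myofibroblast array. Not past the test were the smooth muscle list (4 of 7 higher, 3 lower, 4 and 3 adjusted over the list alone, camera adjusted p = 0.376), pericyte genes (1 of 10 higher, 1 lower, 1 and 1 adjusted over the list alone, 0.644) and the alveolar fibroblast list (1 of 13 higher, 5 lower, 2 and 6 adjusted over the list alone, 0.154). Quantile normalization gave the alveolar fibroblast list an adjusted p of 0.0192. Integrins (5 of 16 higher, 5 lower, 5 and 5 adjusted over the list alone, 0.973, down, though the mean was 0.01), the interferon list (2 of 12 higher, 0 lower, 2 and 0 adjusted over the list alone, 0.664) and metabolism (3 of 14 higher, 1 lower, 3 and 1 adjusted over the list alone, 0.304) did not pass either. Cd248 was higher by 4.36 ± 0.24 (adjusted p = 0.000335), while Itga8 at 0.08 ± 0.31 and Tcf21 at -0.02 ± 0.53 did not differ past the test (adjusted p = 0.858 and 0.985).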

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

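The tests on sex-linked genes, on Spp1 and on RNA of other lung cells were chosen after the result was seen, and the others on the spread of the fibroblast arrays before. Probes with no gene name here, which no comparison above used, carried signal. This is a signal in data outside the comparisons. Over the arrays, 60.1% of their readings were well above background, against 0.703% for the 308 negative control spots. By limma, 2358 of 13852 tested ones differed between myofibroblasts and fibroblasts, 729 higher and 1629 lower in myofibroblasts. Between fibroblasts and homogenate 1298 of 14887 differed, and between myofibroblasts and homogenate 2594 of 14809. Among named genes 17.2%, 19.9% and 26.9% of those tested were called in these comparisons.

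The homogenates labelled male read Xist on both arrays and 3 of 4 Y-linked genes on neither. An exchange of homogenate and sorted samples is argued against by the endothelial list, which lay higher in homogenate by a median of 7.61 on the log2 scale. Female lungs may be the source of the homogenate RNA, but Eif2s3y, the 1 Y-linked gene read there, stood at 6.97% of the sorted arrays, above the 2% set as the bound for it and under the 10% set against it. Dilution of Y-linked transcripts of fibroblasts in whole lung may contribute only if few other lung cells express these genes, which was not tested. With signals under the floor put at the floor, the Y-linked genes had a median of 4.46% of the fibroblast level. Of the 1376 other genes called higher in fibroblasts (median 25.9%), 14 were as low. Ddx3y, at most 1.73%, lay below the lowest of the 1376 (Dner at 1.90%). Dilution cannot raise Xist, which was at least 490-fold higher in homogenate than on the sorted arrays. The Xist values therefore argue against dilution as the whole cause. How far dilution lowers the Y-linked genes stays open, as 3 of the 4 genes lie near the floor. Female lungs as the source stay open, and so does a mix of animals, which was not tested.

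The fibroblast arrays lay further apart than those of the other groups, and dim probes are argued against as the whole cause by the brightest quartile, where the SD was still 2.05 times that of the next noisiest group. RNA of other lung cells in unequal amounts stays open, since 14.1% of the genes over 2-fold apart were over 2-fold higher in homogenate, against 10.2% of all genes and 50% set for it as the main cause, while the 278 genes over 8-fold higher in homogenate went both ways, with a median shift of 0.13 (quartiles -0.40 to 0.74) against 0.16 for all genes. The test chosen before, the share of the genes over 2-fold apart that were called lower in fibroblasts (3.79%), decides nothing, because a wide spread itself prevents calls. Different mixes of fibroblast subsets may contribute, and cannot be told apart from chance here, since the alveolar and adventitial lists shifted apart by 0.45 where random lists of these sizes gave a median of 0.25 and an upper bound of 0.86. The difference between the fibroblast arrays also changed with signal. Its median, replicate 1 minus 2 on the log2 scale, was -0.07 in the dimmest quartile and 0.40 in the brightest. It was 0.04 and -0.04 for the myofibroblast arrays and 0.02 and 0.01 for the homogenate arrays. A constant per array cannot remove such a shift, and its cause was not tested. No biological explanation beyond those named above was tested.

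Spp1 is also a gene of macrophages, which the lineage-negative gate would remove if its antibodies cover them, and this was not checked. Macrophages carried into the sort could raise it, but Spp1 stood at 4413% of its homogenate level in myofibroblasts, while the 12 genes of the macrophage and monocyte list had a median of 0.881%. The highest of these were Csf1r at 92.4%, by a probe that did not differ between the groups, Cd68 at 8.44% and Cd14 at 7.41%, and 7 of the 12 were well above background on both myofibroblast arrays. Untreated lung is the reference here, so macrophages changed by bleomycin were not measured. The gate and the treatment, which changed together, stay open as untested explanations.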

How the results depend on the processing

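Array weights per group and the removal of genes over 2-fold apart between the fibroblast arrays were chosen after the result was seen. Counts of called genes moved by over 1.5 times under some settings, in the order myofibroblasts against fibroblasts, fibroblasts against homogenate and myofibroblasts against homogenate. With only genes well above background on all 4 arrays, so fewer genes tested, they were 1821, 1834 and 2760, and at an adjusted p under 0.01 they were 710, 1726 and 2073. With only the 4 compared arrays the first was 1061 and the third 7287, and with array weights 1142 and 7794, settings that change which arrays set the spread. Leaving out 1 array gave 884 to 5605, 1420 to 6148 and 1724 to 7287, where a lone array is assumed to vary like the other groups. The replicate number as a block gave 2227, 3219 and 4044. Normexp, quantile and median scaling, the authors' table, a floor, other probe rules, no filter, the variance trend and the removal of genes over 2-fold apart stayed within 1.5 times. With an estimated correlation 0, 0 and 0 gene lists passed camera, where 5, 15 and 15 had an unadjusted p under 0.05 and fry passed 16, 27 and 26. The Wnt, Hedgehog and BMP list turned from down to up with fry (adjusted p = 0.0284, against 0.608), and the cause was not tested. No named gene turned direction where it was called in the main fit or under the alternative. The direction of genes called in neither was not compared. In the mean of the probes of a gene 2 called genes of the third comparison turned. Values of named genes under the alternatives kept their side of the threshold 2417, 2689 and 2526 times, lost the call 298, 113 and 120 times and gained one 38, 22 and 37 times. Gene list tests lost the call 17, 49 and 26 times and gained one 15, 5 and 3 times. Signal over background limits the folds of 476, 978 and 1060 called genes, which are bounds.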

Other observations

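Both gene lists here were chosen after the largest changes were seen, and both tests before the result was seen. Thbs4 and Kif26b, among the highest genes in myofibroblasts, raised the hypothesis of a wider rise of tendon and cartilage genes. Of 12 tested genes, 7 were higher and 0 lower, with unadjusted p = 4.58e-05 by camera with a preset correlation and unadjusted p = 0.0443 with an estimated correlation. With an estimated correlation 5 fixed lists also had an unadjusted p under 0.05 in this comparison, and none passed once adjusted over the lists. Scx, a transcription factor of tendon, rose by 5.34 ± 0.69 (log2, SE, adjusted p = 0.00874 by limma), Runx1 by 4.19 ± 0.27 and Cilp, a cartilage matrix protein, by 2.43 ± 0.27. Runx2, a transcription factor of bone, was at least 17.8-fold and Acan (aggrecan) at least 3.23-fold higher. Sox9 at 0.64 and Alpl at -2.0 did not pass (adjusted p = 0.348 and 0.189). Neither did Mkx at 0.98, Chad at 0.28 and Bglap at 0.54 (adjusted p = 0.1565, 0.567 and 0.619). The list also holds genes of bone such as Runx2, so its result is not particular to tendon and cartilage. The hypothesis was found and tested on the same arrays.

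Lrat and Adh7, among the lowest genes, raised the hypothesis of a wider loss of retinoid handling genes, which the list test did not bear out (unadjusted p = 0.917 by camera, and 0.919 with an estimated correlation). Of 13 tested genes, 4 were lower and 2 higher, with a median of 0.33 and a 95% interval from -2.13 to 1.18. The interval is over the genes, taken as independent, and does not measure the spread between samples. Rbp4, a retinol carrier, stood at -4.41 ± 0.25, Dhrs3 at -3.07 ± 0.28 and Aldh1a1 at -1.57 ± 0.23, while Stra6, a retinol transporter, was at least 8.27-fold higher and Cyp26b1 rose by 1.94 ± 0.39. A median near 0 over genes that go both ways decides nothing, so this may hold for part of the genes only.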
